A study of Mus musculus with 6 samples.

How the data were processed

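The samples were whole brains of mouse embryos on a 129SvEv background with a minor 129SvJ part, per the labels. They came from Top2b+/+ embryos and from top2b-/- embryos, which lack DNA topoisomerase IIβ, an enzyme that passes one DNA double strand through another. The ages were E14.5, E16.5 and E18.5, with 1 Affymetrix MG_U74Av2 array for each genotype at each age, 6 arrays in all. Biotin-labelled cRNA made by in vitro transcription from Trizol and RNeasy extracts was hybridised, and the Rosetta Resolver system was used by the submitters, per the labels and the design text. The labels give male sex for 5 of the arrays and female sex for the top2b-/- array of E16.5. Whether an array held RNA of 1 brain or of several is not given in the sources used here.

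The deposited values are linear intensities, 1 per probe set, of which 16.5% to 18.7% per array lay below 0. How the authors summarised probes into these intensities, and whether the arrays were scaled to one another, is not given in the sources used here. The deposited medians of the 12422 probe sets that are not spike-in or other control probe sets were 83.2, 55.5 and 78.0 in the Top2b+/+ arrays, from the youngest age to the oldest, and 78.0, 81.2 and 82.8 in the top2b-/- arrays. As these did not lie within 10% of each other, each array was scaled to the common median, with factors from 0.919 to 1.38 (the highest for the Top2b+/+ array of E16.5). Values were then floored at the pooled 20th percentile, an intensity of 2.39, and put on the log2 scale. Probe sets below the 40th percentile of the mean log2 value (an intensity of 37.0) were left out, which left 7453 for the tests. No detection calls were used, and a noise limit was set after the data were seen: on each array, the size of its 5th percentile (26.9 to 40.7 after scaling), since negative values show the spread of signal around 0. Where all arrays on one side of a comparison lay within that limit, or where raising readings to it moved the fold by over 1.5 times, a fold was given as "at least N-fold", with every value below the limit raised to it. Counts of probe sets or genes at least 2-fold apart used the values floored at 2.39, unless the noise limit is named.

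Gene names came from the platform's annotation, updated by Entrez ID with a RefSeq gene table of the mouse assembly GRCm38.p6, which matched 10817 probe sets. Of the 12422 probe sets, 10833 had 1 gene symbol, 396 had several and 1193 had none, and only those with 1 symbol were named. Gene lengths and chromosomes came from the same table. Where a gene had several probe sets, the gene lists and counts of genes used the one with the highest mean, which gave 5696 genes.

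Tests used limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend) with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The genotype effect (top2b-/- minus Top2b+/+) and the age effect (E18.5 minus E14.5) came from 1 model over all 6 arrays with genotype and the 3 ages as terms, which leaves 2 residual degrees of freedom. The genotype by age interaction was the difference between genotypes in log2 change per day. With 1 array per genotype and age, the ages were the only replication of the genotype effect and the genotypes the only replication of the age effect. The residual spread therefore mixed array noise with true differences between ages, and the p-values speak only of these arrays. Differences within 1 age had no replicates and were given as values, with counts of probe sets at least 2-fold apart.

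Fixed before the data were examined were 30 gene lists covering pathways, neuronal genes and cell types of the embryonic brain and its surroundings. Of these, 27 had at least 5 measured genes and were tested with limma's camera (preset correlation 0.01), with camera with an estimated correlation, and with fry. Lists of choroid plexus (4 measured genes), pituitary (4) and sex-linked genes (3) were too small to test. At each age, a list's median difference was placed among 10000 random lists of the same size matched on mean signal, as a description of that pair of arrays. Also fixed beforehand was the rule for named genes. Top2b came first. For each test, up to 10 highest and 10 lowest changes past the threshold were named, filled to 5 per direction with the smallest p among probe sets that moved one way at all 3 ages (genotype) or in both genotypes (age), and said not to pass. At each age the 5 largest differences in each direction were named, among probe sets above the floor on both arrays, and each list described has 2 to 4 members named.

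The model was tested on simulated arrays with the real means and spreads of the 7453 probe sets, in 5 runs with 200 changed probe sets each. For the genotype effect it recovered 69.2% of probe sets changed 2-fold and 96% of those changed 4-fold, and 7.04% of its calls were false. Camera found a 33-gene list shifted by -0.40 on the log2 scale in 20 of 20 simulations of the 5696 genes. The simulated spread held no correlation between genes and no true difference between ages, and recovery with such structure was not measured. The 200 changes ran up to 16-fold, and many large changes make the adjusted threshold easier to pass. The recovered shares therefore need not hold for the real data, where 3 probe sets passed and Robo1, 4.26-fold lower, did not.

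Alternatives fixed beforehand were quantile normalization, no scaling, other floors and filters, other variance priors, other thresholds, 1 probe set per gene, other codings of age and genotype, and leaving out each pair of arrays. Figures were drawn with matplotlib 3.10.9. The number of arrays limits the precision of every value.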

Results

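Messenger RNA of whole brains was measured on 6 oligonucleotide arrays, 1 for each of the 2 genotypes at E14.5, E16.5 and E18.5, to compare gene expression with and without topoisomerase IIβ while the brain forms. On the log2 scale, arrays correlated across probe sets at 0.905 to 0.952, and the 2 arrays of E18.5 were the closest pair. Each value below comes from 1 array or from the fit over all 6.

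Top2b itself, the targeted gene, had intensities of 585, 204 and 333 in the Top2b+/+ arrays, from the youngest age to the oldest, against 49.1, 48.4 and 37.2 in the top2b-/- arrays. Its 1 probe set was 8.68-fold lower in top2b-/- brains (log2 difference -3.12 ± 0.22 SE, limma, adjusted p = 0.0355, lower at all 3 ages). After scaling, the top2b-/- readings of 48.1, 45.6 and 34.4 lay only just above the noise limits of those arrays, 39.4, 40.7 and 32.4. The size of the fold therefore depends on signal near the noise. Whether the probes lie inside the deleted part of the gene is not given in the sources used here. The other topoisomerases did not differ past the threshold, with log2 differences of 0.04 ± 0.13 for Top1, -0.05 ± 0.15 for Top2a, -0.06 ± 0.12 for Top3a and 0.12 ± 0.14 for Top3b. Sex-linked transcripts matched the labelled sexes. Xist, the RNA that coats the inactive X chromosome, read 810 on the top2b-/- array of E16.5, labelled female, and at most 14.2 on the others, while the Y-linked Eif2s3y read 13.7 there and 122 to 216 elsewhere.

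Only 3 of 7453 probe sets differed between genotypes past the threshold, 1 higher and 2 lower in top2b-/- brains. Elovl1, a fatty acid elongase for very long chains, was 10.7-fold higher (log2 3.42 ± 0.22 SE, adjusted p = 0.0355), with intensities of 891, 533 and 1157 against 133, 32.6 and 71.8. Cacna2d3, an auxiliary subunit of voltage-gated calcium channels, read 197, 221 and 313 in Top2b+/+ brains and lay within the noise at every age in top2b-/- brains. It was at least 6.88-fold lower (adjusted p = 0.0355), and Top2b was the other lower gene.

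Next in order of p, and not past the threshold, came further neuronal genes that were lower at all 3 ages. Robo1, a receptor for Slit guidance cues, had a log2 difference of -2.09 ± 0.20 (adjusted p = 0.103). Ctnna2, the neuronal α-catenin, had one of -2.30 ± 0.23 (adjusted p = 0.108) on one probe set, with -1.84 ± 0.39 and -1.52 ± 0.21 on its 2 others, and Myt1l, a zinc finger transcription factor of neurons, one of -1.59 ± 0.15 (adjusted p = 0.103). In the higher direction, also not past the threshold, Nrsn1 had 0.89 ± 0.14, the growth factor Igf1 0.89 ± 0.14 and the kinase Dyrk1a 0.75 ± 0.14, with adjusted p from 0.233 to 0.361. The pseudogene Tyms-ps read 762, 431 and 151 in top2b-/- brains and lay within the noise in all Top2b+/+ arrays, at least 11.6-fold higher (adjusted p = 0.278). With no noise limit applied, 23 probe sets were at least 2-fold lower at every age, against 2 that were higher, Elovl1 and Tyms-ps. The lower ones, chosen by that count and not by the rule for named genes, were 3 probe sets of Ctnna2 and 1 each of Cacna2d3, Cdh13, Top2b, Ebf1, Cplx1, Syt2, Arf3, Cacna2d1, Cdh8, Robo1, Nell2, Prss29, Tenm2, Ncam2, Wdr5, Grid1, Myt1l, Alcam, Ptcra and Pbx3. Several of them encode adhesion molecules or calcium channel subunits, and no enrichment was tested on this group. At E14.5 the top2b-/- readings of Syt2, Ncam2 and Wdr5 lay within the noise, as did those of Grid1 and Ptcra at E16.5. With these readings raised to the noise limit, the differences were under 2-fold. A 2-fold difference at every age is therefore not shown for all 23.

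The count of 3 moved with the setting. It was 110 without scaling the arrays (40 higher, 70 lower), 0 with no filter on dim probe sets, 0 without the intensity trend, 14 without the E14.5 pair, and 0 without the E16.5 or the E18.5 pair. With the stricter filter, which removes Top2b and Cacna2d3, 4 passed: Elovl1, Robo1, Myt1l and Ctnna2. At an unadjusted p under 0.05 there were 488 probe sets against 373 expected by chance, 164 higher and 324 lower.

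**Figure D1:**
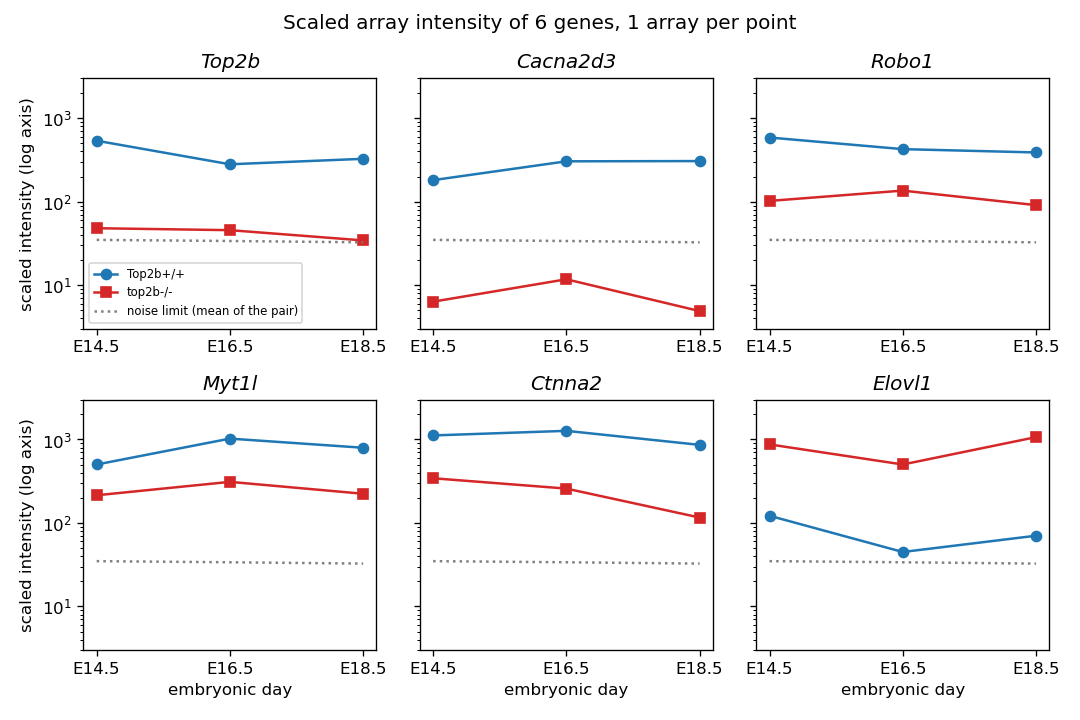
Scaled intensity on a log axis against embryonic day for Top2b, 4 other genes lower in top2b-/- brains (Cacna2d3, Robo1, Myt1l, Ctnna2) and Elovl1, which was higher; blue circles are Top2b+/+, red squares are top2b-/-, each point is 1 array, and the dotted line is the mean noise limit of the 2 arrays. The genotypes do not cross at any age, and Cacna2d3 lies within the noise in all 3 top2b-/- arrays, while only Top2b, Cacna2d3 and Elovl1 passed the test.

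Among the gene lists, axon guidance and adhesion genes had the smallest p and were lower in top2b-/- brains. Of 33 measured, 29 had a lower value, with a median log2 difference of -0.48 (camera adjusted p = 1.49e-14; adjusted p = 0.744 with an estimated correlation). None passed over all probe sets, and 14 were lower when adjusted over the list alone. The cadherin Cdh13 was at least 3.82-fold lower and the adhesion molecule Ncam2 at least 2.31-fold lower, both within the noise in all 3 top2b-/- arrays, and Cdh8, another cadherin, had a log2 difference of -2.19 ± 0.37. Dcc, the receptor for netrin, had -1.27 ± 0.23.

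Synaptic vesicle and neuronal maturation genes were lower too, 27 of 33, with a median of -0.17 (camera adjusted p = 5.24e-08; adjusted p = 0.744 with an estimated correlation), although none passed, either over all probe sets or adjusted over the list alone. The complexin Cplx1 was at least 3.19-fold lower, with its E14.5 reading in top2b-/- brains within the noise. The calcium sensor Syt1 had -1.49 ± 0.32 and the neurofilament Nefm -1.15 ± 0.39. Of 6 glutamate receptors and transporters, 4 were lower (median -0.57, camera adjusted p = 0.0191), and 2 of these passed adjusted over the list alone, Grik2 (-1.31 ± 0.29) and Gria1 (-0.70 ± 0.18). Of 13 ion channel genes 8 were lower (median -0.18, camera adjusted p = 0.0219), but their median was 0.12 at E16.5, against -0.21 at E14.5 and -0.35 at E18.5. The mean of this list was -0.72, as a few members such as Cacna2d3 lay far below the rest. Cacna2d3 passed over all probe sets, and 3 passed adjusted over the list alone, Cacna2d3, Cacna2d1 (-2.21 ± 0.35) and the potassium channel Kcnma1 (-1.19 ± 0.27). For both lists the adjusted p with an estimated correlation was 0.744, and both calls ended without the E18.5 pair (adjusted p = 0.0946 and 0.0866), that of ion channels also without the E14.5 pair (median -0.04, adjusted p = 0.0597).

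Glycolysis and hypoxia genes were lower in 17 of 19 cases, by little (median -0.24, camera adjusted p = 0.000545), with Ldha at -0.62 ± 0.21 and Ndrg1 at -0.56 ± 0.18. Of 12 astrocyte markers 10 were lower (median -0.31, camera adjusted p = 0.0454), among them the water channel Aqp4 (-0.91 ± 0.37) and the lipid carrier Apoe (-0.62 ± 0.31). In neither list did a gene pass, over all probe sets or over the list alone, and the adjusted p with an estimated correlation was 0.744 for each. The astrocyte call ended without the E16.5 pair (adjusted p = 0.544), whose median was -0.61, against 0.01 at E14.5 and -0.11 at E18.5. With fry, which asks whether a list moves one way without setting it against other genes, no list passed (lowest adjusted p = 0.0632, topoisomerases). That list holds Top2b, the targeted gene itself. Without scaling the arrays, the median genotype difference of all genes was 0.19, a shift that moves every list alike and leaves its place among other genes unchanged. The unscaled list medians were -0.30 for axon guidance, 0.01 for synaptic genes, -0.39 for glutamate receptors, -0.00170 for ion channels, -0.06 for glycolysis and -0.13 for astrocytes. After quantile normalization, with a median of 0.03 over all genes, they were -0.47, -0.15, -0.54, -0.18, -0.18 and -0.28.

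The other 21 lists did not pass, with camera adjusted p from 0.0531 to 0.968. They were Cajal-Retzius and reelin pathway genes, cell cycle, cerebellar, endothelial, erythroid, GABA and interneuron, housekeeping, Hox and patterning, hypothalamic, immediate early, meningeal, microglial, monoamine and cholinergic, muscle and head tissue, neurogenic, oligodendrocyte, oxidative phosphorylation, p53, radial glia, ribosomal and topoisomerase genes. Leaving out a pair brought some past the threshold: meningeal and oxidative phosphorylation genes were lower without E14.5 (adjusted p = 0.0237 and 0.0251), GABA and interneuron genes lower without E16.5 (adjusted p = 0.0126) and monoamine genes higher without E18.5 (adjusted p = 0.0376). Single members passed when adjusted over their own list alone. Lower were the layer-patterning glycoprotein Reln (-0.98 ± 0.12), the transcription factors Ebf1 (at least 4.38-fold, within the noise on 2 top2b-/- arrays) and Ebf2 (-0.76 ± 0.13), and among interneuron genes the peptides Sst (-1.49 ± 0.25) and Npy (-1.06 ± 0.27) with the receptor subunits Gabra2 (-0.98 ± 0.25) and Gabrb1 (-0.71 ± 0.20). Higher were the calcium buffer Calb1 (0.99 ± 0.21) and the transcription factor Neurod1 (0.81 ± 0.17). Of 36 cell cycle genes 21 were higher and 15 lower, with a median of 0.03. The median and the mean or the test had opposite signs for the cell cycle, cerebellar, Hox, microglial, muscle, neurogenic and radial glia lists.

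Within single ages, 2-fold differences numbered 145 higher and 168 lower at E14.5, 217 higher and 340 lower at E16.5, and 122 higher and 192 lower at E18.5, with no replicates and so no test. Without a filter on dim probe sets the totals were 1666, 2099 and 1493 against 313, 557 and 314, and they were 152, 361 and 205 among probe sets above the noise limit on both arrays. In all but 3 genes, one array of the named pairs lay within the noise, so the folds are lower bounds. At E14.5 Cacna2d3 was at least 4.60-fold, Plekho1 4.60-fold, Grb7 3.67-fold, Myh14 2.72-fold and Rsph1 2.47-fold lower, and Aprt was at least 8.21-fold, Padi2 6.84-fold, Pias2 6.17-fold, Dhps 4.19-fold and Dmtn 2.59-fold higher. At E16.5 Ptgds, the prostaglandin D synthase of the meninges, read 52.3 against 649 on one probe set and 82.2 against 926 on another. Rbfox2, a splicing factor, was at least 16.8-fold lower, Cacna2d3 7.48-fold and Cdh13 4.60-fold. Higher at that age were Tyms-ps (at least 15.1-fold), Got2 (at least 11.2-fold), Elovl1 (533 against 32.6), Rgs14 (171 against 10.6, the latter within the noise) and Gstm3 (at least 2.79-fold). At E18.5 Cacna2d3 was at least 9.47-fold lower, Ebf1 4.45-fold, Epha5 2.97-fold and Pcbd2 2.61-fold, and Top2b read 37.2 against 333. Higher were Elovl1 (1157 against 71.8), the hormone precursor Pomc (at least 5.75-fold), Myoz1 (5.06-fold), Tyms-ps (4.24-fold) and Tbxa2r (2.15-fold).

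The axon guidance list had median differences of -0.30, -0.45 and -0.69 at E14.5, E16.5 and E18.5, each below all 10000 random lists matched on mean signal. Synaptic genes had -0.11, -0.44 and -0.27, at percentiles of at most 0.04. At E16.5 several non-neuronal groups were also low in the top2b-/- array, with medians of -0.82 for microglia and macrophages (percentile 0.03), -0.78 for meninges (below all random lists) and -0.49 for erythroid genes (percentile 0.44). At E18.5 the microglial median was 0.35 (percentile 99.61). Cell cycle genes had medians of 0.05, 0.06 and 0.05, at percentiles between 43.8 and 91.7.

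**Figure D2:**
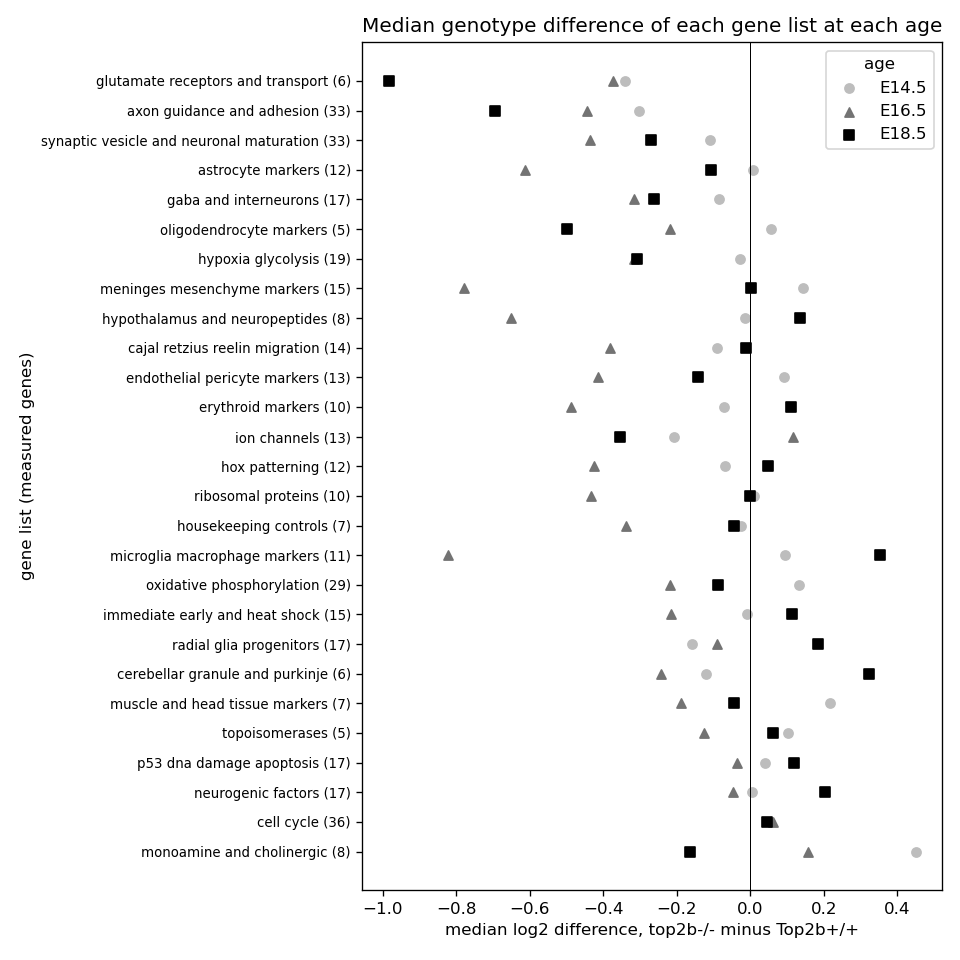
Median log2 difference, top2b-/- minus Top2b+/+, of each of 27 gene lists (measured genes in brackets) at E14.5 (light circles), E16.5 (grey triangles) and E18.5 (black squares), each from 1 array against 1 array. Axon guidance, synaptic and glutamate receptor lists lie below 0 at all 3 ages, as low as -0.98 for glutamate receptors at E18.5. So do the GABA, Cajal-Retzius, glycolysis and housekeeping lists. Many non-neuronal lists lie lowest at E16.5, as does the synaptic list.

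Between E14.5 and E18.5, genes of cell division and embryonic globins fell and some astrocyte genes rose, in both genotypes. Of 7453 probe sets 111 passed, 44 higher and 67 lower at E18.5. The embryonic globin Hbb-y fell 127-fold on one probe set (log2 -6.98 ± 0.52 SE, adjusted p = 0.0232) and at least 155-fold on another, and Hba-x fell 49.0-fold (log2 -5.62 ± 0.23, adjusted p = 0.00528). The Notch ligand Dll1 fell 5.51-fold, and the cell division genes Ccna2, Bub1, Cdk1 and Ckap2 fell 5.20-fold, 5.02-fold, 4.79-fold and 4.53-fold. The DNA repair gene Rad51ap1 fell at least 3.80-fold and the zinc finger gene Zfp94 at least 10.9-fold, both to within the noise. Genes that rose included Aqp4 (at least 7.95-fold), the metallothionein Mt1 (7.82-fold), Apoe (7.41-fold), Cx3cl1, a chemokine made by neurons (by 2.32 on the log2 scale), Ramp1 (5.22-fold), Lmo7 (4.61-fold) and the malic enzyme Me1 (at least 2.91-fold). Clu rose at least 3.50-fold, Kcne1l at least 3.59-fold and the endocytic adaptor Dab2 at least 1.83-fold, each from within the noise at E14.5, and the calls of Clu, Dab2 and Me1 ended when low values were raised to the noise limit (adjusted p = 0.0562, 0.233 and 0.0807). The named genes had adjusted p from 0.00528 to 0.0495, and each changed the same way in both genotypes. After quantile normalization 267 passed, with the balance turned to 154 higher and 113 lower, and without scaling 198 were higher and 154 lower. Only 4 passed with no filter, 0 without the intensity trend and 3 without the E16.5 pair.

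Cell cycle genes made the clearest list. Of 36 measured, 35 had lower values at E18.5, 21 fell past the threshold and 34 did so adjusted over the list alone (median -1.45, camera adjusted p = 2.85e-26; adjusted p = 0.165 with an estimated correlation). Top2a, the topoisomerase II of dividing cells, fell by 2.05 ± 0.18 on the log2 scale, and Kif20a fell by 1.97 ± 0.19. In the neurogenic list 13 of 17 were lower (median -0.45, adjusted p = 0.0101), and Dll1 and Neurog2 (-1.98 ± 0.20) fell. In the topoisomerase list 4 of 5 were lower (median -0.49, adjusted p = 0.0337) and Top2a fell, while Top2b had -0.60 ± 0.27. Erythroid genes had a median of -0.12 and a mean of -1.55 (adjusted p = 0.0439), with Hbb-y and Hba-x the 2 that fell and adult Hbb-b2 at -0.10 ± 0.16. With an estimated correlation the adjusted p was 0.607 for the neurogenic and topoisomerase lists and 0.635 for the erythroid list.

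Several neuronal lists and the astrocyte list were higher at E18.5. In the synaptic list 30 of 33 were higher (median 0.43, adjusted p = 1.34e-10), 5 rose past the threshold and 13 adjusted over the list alone, among them Eno2 (1.43 ± 0.14), Snap25 (1.04 ± 0.13) and Camk2b (1.05 ± 0.12). Of 12 astrocyte markers 11 were higher (median 0.91, adjusted p = 4.45e-06), and Aqp4, Mt1 and Apoe rose. Of 17 GABA and interneuron genes 15 were higher (median 0.87, adjusted p = 4.68e-06), and the vesicular transporter Slc32a1 rose (0.92 ± 0.13). Smaller shifts upward passed for ion channels (median 0.37, adjusted p = 0.0337; Cacna1b 0.89 ± 0.26), hypothalamic peptides (0.41, adjusted p = 0.0411; Cck rose by 1.91 ± 0.22), glutamate receptors (0.35; Gria1 0.96 ± 0.22), glycolysis (0.29; Ndrg1 1.39 ± 0.22), immediate early genes (0.08; Egr1 at least 2.46-fold, not past the threshold) and axon guidance (0.08; Ptprz1 rose by 0.96 ± 0.12), with adjusted p = 0.0439 for each of the last 4 lists. With an estimated correlation none of these rising lists passed, with adjusted p from 0.448 to 0.635. With fry only the GABA and interneuron list passed among them (adjusted p = 0.00326), while synaptic genes had 0.139 and astrocyte markers 0.152. Without the E16.5 pair the axon guidance, glutamate receptor, glycolysis and immediate early lists lost their call (adjusted p from 0.0581 to 0.0709) and ribosomal genes were lower (adjusted p = 0.0121). After quantile normalization 6 of the 13 lists kept their call: cell cycle, synaptic, astrocyte, GABA, neurogenic and topoisomerase genes. The other 14 lists, namely the Cajal-Retzius, cerebellar, endothelial, housekeeping, Hox, meningeal, microglial, monoamine, muscle, oligodendrocyte, oxidative phosphorylation, p53, radial glia and ribosomal lists, had camera adjusted p from 0.133 to 0.940. Of these the cerebellar list passed with fry (adjusted p = 0.0456). The median and the mean or the test had opposite signs for the endothelial, housekeeping, Hox and monoamine lists.

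No gene was found to change with age differently in the 2 genotypes. The interaction test in limma passed 0 of 7453 probe sets (lowest adjusted p = 0.764), with 317 at an unadjusted p under 0.05 against 373 expected by chance. Without scaling the arrays 50 passed. The smallest p belonged in the upward direction to Grb7, Tef, Phf1, Rnf7 and Gon4l, whose log2 difference per day was 0.56 to 1.55 more in top2b-/- brains. In the other direction they belonged to Vcp, Ptprg, Zfpm1, Hps4 and Fbxo6, with -0.65 to -1.12 per day. The slopes of Grb7, Tef, Phf1, Vcp, Zfpm1 and Hps4 rest in part on readings within the noise. Under the alternatives that of Grb7 was as small as 1.08 per day and that of Zfpm1 -0.39. For Ptprg, a receptor tyrosine phosphatase, the genotype difference was 0.28 at E14.5, -1.59 at E16.5 and -2.33 at E18.5.

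Genes higher at E16.5 than at E14.5 in the Top2b+/+ arrays tended to be lower in the top2b-/- array of E18.5 than in its Top2b+/+ partner. Across 5696 genes, the change from E14.5 to E16.5 in Top2b+/+ brains and the genotype difference at E18.5, which share no array, had a Spearman rho of -0.228 and a Pearson r of -0.142. Genes are not independent replicates, so this describes these 4 arrays. Of 278 genes at least 2-fold higher at E16.5, 63.0% had a lower value in the top2b-/- array of E18.5 (median -0.16), and 7.55% were at least 2-fold lower against 2.41% of all genes. The 173 genes at least 2-fold lower at E16.5 had a median of 0.11, and 13 of them were at least 2-fold lower and 6 at least 2-fold higher, so the excess of 2-fold lower values was not particular to rising genes. When the developmental change was taken from the top2b-/- arrays, rho was -0.0233 and 51.5% of rising genes were lower. The tendency therefore rests on the Top2b+/+ arrays of E14.5 and E16.5.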

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

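Control probe sets for 18S ribosomal RNA, which no comparison used, gave more signal in the top2b-/- array at each age. The 5' part read 675, 133 and 5254 in the top2b-/- arrays, from the youngest age to the oldest, against 87.7, 27.5 and 131 in the Top2b+/+ arrays. The 3' part read 322, 274 and 490 against 214, 126 and 186, and the middle part lay below 0 on all 6 arrays. The 3' to 5' signal ratio of the mRNA Actb was 1.08, 1.19 and 1.13 in the top2b-/- arrays against 1.11, 1.04 and 1.03, and that of Gapdh 0.827, 0.935 and 0.815 against 0.806, 0.953 and 0.906. No explanation of the ribosomal signal was tested, nor whether a difference in RNA preparation bears on the genotype differences of genes and gene lists above.

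For 2 gene lists the genotype difference lay in opposite directions at E14.5 and E18.5, each beyond the middle 95% of random lists at both ages. Oxidative phosphorylation genes had a median of 0.13 at E14.5 and -0.09 at E18.5, a change of -0.22. Radial glia and progenitor genes had -0.16 and 0.18, a change of 0.34. Each age held 1 array per genotype, and the difference between the ages was not tested.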

How the results depend on the processing

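Without scaling the arrays the genotype effect had 110 probe sets instead of 3, the age effect 352 instead of 111 and the interaction 50 instead of 0, and quantile normalization gave 267 for the age effect. With no filter on dim probe sets the counts were 0 for genotype and 4 for age, and without the intensity trend 0 and 0. The stricter filter gave 225 for age, embryonic day as a number 175 and an adjusted p under 0.1 473. Leaving out 1 pair of arrays gave 0 to 14 for genotype, and 3 for age without the E16.5 pair. Fewer arrays were then fitted, with 1 residual degree of freedom for genotype, so the spread drew also on all probe sets together. The 2-fold counts at E14.5, E16.5 and E18.5 were 1666, 2099 and 1493 with no filter, 55, 168 and 94 with the stricter filter, 909, 1565 and 893 at 1.5-fold, 136, 198 and 111 at 3-fold, and 152, 361 and 205 above the noise limit on both arrays. The rho of developmental change and genotype difference was -0.458 with the change from E14.5 to E18.5 in Top2b+/+ brains, which shares an array with the difference: its r was -0.40, and simulated arrays with no effects gave -0.505, while the covariance was -0.126 against a simulated -0.0846, so what lies beyond the shared array was left open. It was -0.0233 with the top2b-/- change to E16.5, -0.150 with no filter and -0.267 with the stricter filter. With quantile normalization and the top2b-/- change to E18.5 it was 0.210, but that array then enters both quantities with the same sign, which gives a positive value by itself, so the reversed sign is not read as a result. Lists passing numbered 0 for genotype and 0 for age with an estimated correlation, 0 and 5 with fry, and 6 for age after quantile normalization. Apart from fewer genes or arrays tested and shared arrays, the cause was not tested. Of 135 values of the 10 named genotype genes under the alternatives, 107 stayed on their side of the threshold, 14 lost their call and 14 gained one. Of 227 for age 159 stayed and 68 lost it, and of 82 for the interaction 75 stayed and 7 gained one. None of these changed direction. The floor at the noise limit, the counts above that limit, the rho of 0.210 and leaving out the E16.5 pair together with quantile normalization were added after seeing the data. A floor at the 5th percentile, planned beforehand, has no value because that percentile lies below 0. Between 59.4% and 64.5% of probe sets per array lay above the noise limit, which limits what can be said of dim genes.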

Other observations

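Very long genes tended to be lower in top2b-/- brains. Among 5690 genes with a known length, the 117 of at least 300 kb had a median log2 difference of -0.40, and 84.6% of them had a lower value, while genes of under 10, 10 to 30, 30 to 100 and 100 to 300 kb had medians of -0.02, 0.02, 0.03 and 0.01. At an unadjusted p under 0.05, 55 of the 117 were lower (47.0%) and 1 was higher, Pde4b, against 3.66%, 2.75%, 2.30% and 7.27% lower in the shorter groups. They included Cacna2d3 (818 kb), Cdh13, Robo1, Tenm2, Ctnna2, Myt1l, Dcc, Ank3 and Reln, and 43 were lower and 1 higher when adjusted over these 117 genes alone. As the 300 kb limit was chosen after these data were seen, that adjustment is no separate test. Over all probe sets only Cacna2d3 of them passed. At E14.5, E16.5 and E18.5 the medians of the 117 genes were -0.24, -0.45 and -0.48, each below all random lists matched on mean signal, and 56.4% were lower at all 3 ages against 12.1% of genes under 100 kb. Over all lengths the Spearman rho was -0.0794, 0.0628 and -0.0172 at the 3 ages, with no common direction.

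In the axon guidance and adhesion list, the 26 genes of at least 100 kb had a median of -0.65 and the 7 shorter ones -0.05. This was looked at after the pattern was seen and is no separate evidence, since long members such as Robo1, Cdh13 and Dcc are part of it. Top2b (65.6 kb), Elovl1 (6.08 kb), Tyms-ps (1.35 kb) and Arf3 (25.5 kb) show that large differences were not confined to long genes.

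Of the tests below, those of a length effect at 100 kb, all those at 300 kb except the delay of up to 4 days, the count in 1 direction over splits, and the interval used for the stage of the E16.5 pair were chosen only after the result was seen, as was the 300 kb limit itself. At 100 kb, the limit tried first, the 640 genes lay low at all 3 ages (highest percentile 0.38) but by little, with medians of -0.01, -0.10 and -0.07. After quantile normalization, long genes were lower than shorter ones of the same brightness in 12 of 12 combinations of brightness quartile and age at 100 kb and in 12 of 12 at 300 kb, which argues against a signal tied to brightness. Less mature brains stayed open at 100 kb, since long genes with little change in age reached percentile 48.41 at E16.5.

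At 300 kb the percentile was 0 at each age, and 0 also for the 46 genes that changed little with age. That change was averaged over both genotypes, so a gene could rise in Top2b+/+ brains and still be among the 46. Over all 117 genes the median rise from E14.5 to E18.5 in Top2b+/+ brains was 0.33. The 46 genes therefore cannot decide on immaturity. The 117 genes were lower in the top2b-/- array of E18.5 even than in the Top2b+/+ array of E14.5 (median -0.24, below all random lists), which argues against a delay of up to 4 days. A lower share of neurons stays open. The 29 synaptic and maturation genes under 100 kb were lower too, with a median of -0.16, and lay above the long genes by 0.24 (bootstrap interval over genes 0.02 to 0.39). That interval resamples genes read on the same 6 arrays, so it does not measure the spread between brains. At E16.5 the whole synaptic list had a median of -0.44, against -0.45 for the long genes. All or a part of the pattern could come from fewer neurons. The 90 long genes outside the neuronal lists had medians of -0.16, -0.36 and -0.35 at the 3 ages. They still held neuronal genes such as Myt1l and Ctnna2, so they do not decide this. The percentiles restate the pattern and cannot show its cause. The 18S control signal was also higher in each top2b-/- array, and a difference in RNA preparation that moves with genotype was not tested and stays open, as does a need of very long genes for topoisomerase IIβ, which is only a hypothesis from these 6 arrays.

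Elovl1 and Cacna2d3 could differ through DNA that came along with the targeted Top2b allele on chromosome 14. Elovl1 lies on chromosome 4, which argues against this for Elovl1. Cacna2d3 lies on chromosome 14, and for it linked DNA cannot be told apart from an effect of the genotype. Among other chromosome 14 genes under 100 kb, 8 of 157 (5.10%) had an unadjusted p under 0.05 against 248 of 4892 (5.07%) elsewhere (Fisher's exact p = 1), which bounds a wide effect of the chromosome but not a variant in Cacna2d3 itself. Each gene was read by 1 probe set.

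The E16.5 pair held the most 2-fold differences, 557 against 313 and 314. Scaling of the dim Top2b+/+ array as the whole cause is argued against, since the count stayed 1.59 times the higher of the other 2 after quantile normalization. Genes of the X and Y chromosomes are argued against as their source, at 2.21% of the differences and 0.706 times their share of those tested, but effects of sex on other chromosomes were not tested and stay open. An earlier stage of the top2b-/- embryo could not be excluded: rising genes put the Top2b+/+ array ahead by 0.268 of the change from E14.5 to E18.5 (interval 0.190 to 0.346) but falling genes by 0.0588 (-0.0720 to 0.0984). After quantile normalization these leads were 0.190 and 0.0799 (-0.0178 to 0.154).

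The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 3 probe sets for genotype and the highest other split 17, with 5 of 10 splits giving at least 3. For the interaction the real count was 0 and the highest other 7; all 10 of 10 splits must give at least 0, so this count decides nothing. For lower genes at an unadjusted p under 0.05 the real count was 324 and the highest other 734 in 1 direction, with 3 of 10 giving as many. With age in the model, the 6 splits that part the arrays of 1 age only measure the genotype difference of that pair, 2 splits for each age, so they are not chance groupings. The counts of 17 and 734 are those of the E16.5 pair, which also differs in sex. The 3 other splits that part all ages gave 0 probe sets each for genotype, and at most 260 in 1 direction. A true genotype difference adds to their residual spread and lowers these counts, so they cannot measure chance either.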
